A study of Arabidopsis thaliana with 12 samples.

How the data were processed

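Expression was measured in whole seedlings of Arabidopsis thaliana, ecotype Columbia, on Affymetrix ATH1-type 3' expression arrays, which read each gene through 1 or more probe sets. The labels give 12 arrays in 4 groups of 3: wild type, the single mutants sdg8 and hub2, and the double mutant sdg8hub2. Seedlings were 6 days old and grew at 22 °C with 16 h of light and 8 h of dark. Per the labels, the 3 arrays of a group are biological replicates that were grown independently, so p-values measure the spread between independently grown samples. The labels name a labelling kit for these arrays and, in another field, a labelling procedure of a second manufacturer, and which of them was followed is not settled here.

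The deposited values are intensities on a linear scale, 1 column per array. Per the submitters' processing notes, they were made with MAS5 and the affy package, whose versions are not given in the sources used here. In the deposited table the mean intensity after trimming 2% of the values at each end was 500 on all 12 arrays, so the authors' values already share a scale. Raw scanner files and detection calls were not used here, so no probe set has a call of present or absent. The number of arrays limits the precision.

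From there, values were raised to a floor at the 1st percentile of the table, 1.18 intensity units, and taken as log2. Control probe sets were left out (64 of 22810). Probe sets whose mean log2 value over the 12 arrays lay above the 20th percentile, 18.6 intensity units, were kept, which left 18196. A linear model with a mean per group was fitted to all 12 arrays in limma 3.58.1 under R 4.3.3, with moderated variances that follow an intensity trend. All 4 groups share 1 estimate of the spread. The 7 contrasts were each mutant against wild type, the double mutant against each single mutant, sdg8 against hub2, and the interaction (sdg8hub2 minus sdg8 minus hub2 plus wild type on the log2 scale). P-values are two-sided, were adjusted by the Benjamini-Hochberg method over the 18196 probe sets, and were called at 0.05. "Changed", "rose" and "fell" refer to that call.

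Probe sets were named from the supplied platform annotation, updated by gene identifier through a RefSeq gene table of the TAIR10.1 assembly, which was used only for names and gene order. Of the 22810 probe sets, 13513 have 1 gene symbol, 503 have several and 8794 have none there; 13436 of the single-symbol probe sets matched the RefSeq table. Unlisted probe sets are unnamed here, not without a gene, and no gene was named from a probe set with several. Of the probe sets tested, 10230 carry 1 symbol. Probe sets of SDG8, HUB2 and the floral repressor FLC and its relatives are unnamed in the table, so the targeted genes were not checked and those genes were not analysed here. A group mean below the filter value of 18.6 is called near the background here, a choice made without detection calls. A fold against such a mean is poorly determined, and such changes are given also as the difference of log2(intensity + 64). Folds against low means above that value may depend on the background too, but are given on the log2 scale alone.

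Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with the correlation estimated per list beside it, and with fry. For lists, each gene counted once, by its probe set with the highest mean, which left 10120 genes. The lists by gene code held 356 entries in 22 lists, of which 37 entries are named in the annotation and 6 lists have no measured member. Further lists were made by fixed name patterns, and a last set of name patterns was written once the annotation had been seen but before any test was run. Lists of at least 5 measured genes were tested, 29 in all. A name pattern for plant defensins and thionins had also matched methionine and cystathionine genes (18 matched, 4 kept), and one for cytochrome P450 genes had matched cyclophilins (21 matched, 17 kept). These matches were removed after the tests had been seen, a correction that lowered the p of the cytochrome P450 list in the comparisons named next. With all matches left in, that list had a camera adjusted p of 0.0226 in sdg8 against wild type and 0.0256 in sdg8 against hub2, and the smallest adjusted p of the defensin list over the 7 comparisons was 0.0760. With 4 members left, the defensin list was not tested.

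Named genes were chosen by a fixed rule. For each mutant against wild type they are the 8 highest and 8 lowest log2 changes, and for the other comparisons the 5 highest and 5 lowest, among probe sets that changed, have 1 gene symbol, and have a higher group's mean above the median of all probe sets. Except for the interaction, all 3 arrays of 1 group also had to lie on 1 side of all 3 arrays of the other. From lists with a camera call, or with at least 2 changed members, up to 4 members with the smallest p were added. This gave more list members than are printed: the text gives members of the lists with a camera call and of some others, a narrowing made after the values were seen. Of several probe sets of a gene, the rule takes each on its own, and disagreement between them is stated where it occurred.

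Comparisons against wild type share the same 3 wild-type arrays. Overlaps and correlations between them are therefore printed beside values simulated for unchanged groups (100 simulations for correlations and 20 for overlaps of calls). The 3 wild-type arrays could not be split into parts of at least 2. For the additivity of the double mutant, data were simulated with each single mutant's changes shrunk by their estimated error and added, and changed probe sets were called anew in each of 100 simulations. This replaced a simulation that took the estimated changes as true and kept the called probe sets, after that version's result, a slope nearer to 1, had been seen, because it left out the selection of called probe sets. The simulations called 3340 probe sets on average, against 2870 in the data. RNA quality was judged per array by the log2 difference between the 3' and the 5' control probe set of actin and of GAPDH, with exact permutation tests.

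The procedure was tested on simulated data, in which 100 probe sets were changed by 2-fold and 100 by 1.5-fold among the 18196. For sdg8 against wild type it recovered 63 of the 2-fold and 46 of the 1.5-fold changes with 4 false calls. For hub2 it recovered 62 and 48 with 5 false calls, for sdg8hub2 63 and 44 with 6, and for the interaction 42 and 13 with 4. No recovered change had the wrong direction.

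Alternatives covered the scaling between arrays, the filter, a pseudocount, the variance model, the arrays in the fit, the replicate number as a block, array weights, stricter thresholds, each array left out in turn, and the list tests. The removal of a pair of sdg8 arrays, the RNA quality covariate and the lists as first matched were added after the data were seen. The contrasts, the test, the filter, the rule for named genes and the other alternatives were fixed before the data were examined.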

Results

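Transcript levels were compared in 6-day-old seedlings of wild-type Arabidopsis and of 3 mutant lines, with 3 arrays per group. SDG8 encodes a histone H3 methyltransferase, and HUB2 encodes a ligase that attaches ubiquitin to histone H2B. The design sets each single mutant and the double mutant against wild type and allows a test of whether the effects of both mutations add up. Of 18196 probe sets tested, 2598 changed in sdg8, 519 in hub2 and 3367 in sdg8hub2, each against wild type (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 1342, 257 and 1739 carry 1 gene symbol, and the others are unnamed here or have several.

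**Figure D1:**
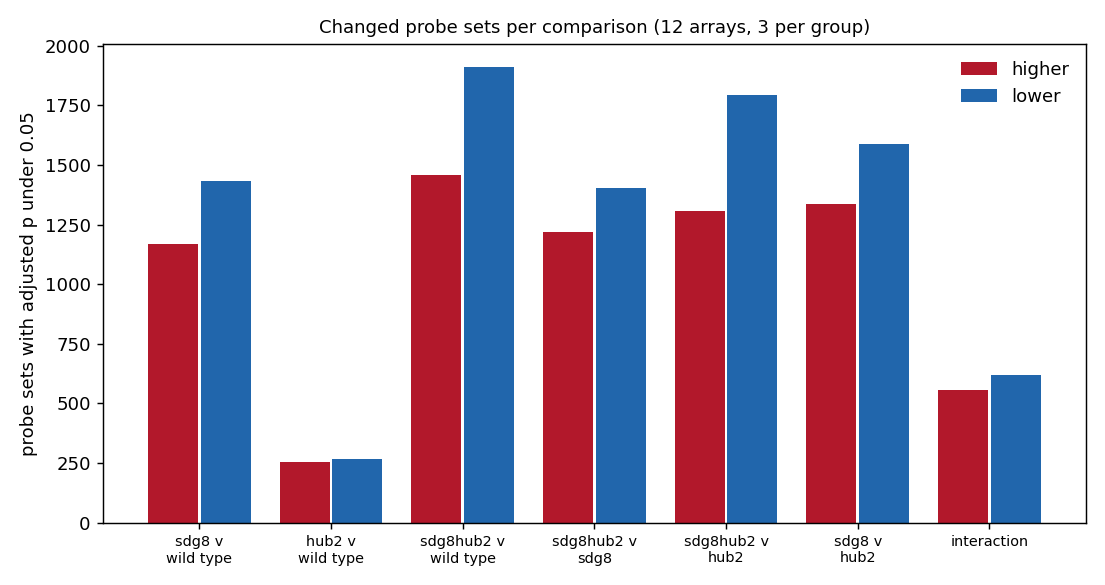
Number of probe sets (y axis) higher or lower at an adjusted p under 0.05 in each of 7 comparisons (x axis), from 12 arrays with 3 per group. The hub2 bars (254 higher and 265 lower) are the shortest, and those of sdg8hub2 against wild type (1457 and 1910) the tallest.

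The comparison of sdg8 with wild type asks which transcripts depend on SDG8. AT2G21640, a mitochondrial protein gene induced by oxidative stress, rose 6.11-fold, from a log2 signal of 7.41 ± 0.19 to 10.02 ± 0.06 (SD, n = 3 in each group). AT5G51440, a mitochondrial small heat shock protein gene, rose 5.87-fold, AT5G09570 rose 5.60-fold and AT2G41730 by a log2 change of 2.17. BHLH101, a transcription factor gene of the iron deficiency response, rose 5.41-fold, from 7.52 ± 0.27 to 9.96 ± 0.20 (SD, n = 3). AT5G14650 rose 5.38-fold, AT1G31690 rose 3.98-fold (a log2 change of 1.53 on its other probe set), and GSTU25, which encodes a tau-class glutathione transferase, rose 3.83-fold. AT2G41730 is read by a probe set of a type that can cross-hybridise.

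Among the genes that fell in sdg8, AT2G43620, a member of the chitinase family, dropped from a log2 signal of 10.61 ± 0.09 to 7.72 ± 0.34 (SD, n = 3), which is 7.40-fold. AT5G39580, a class III peroxidase gene, fell 6.22-fold and AT2G41120 fell 6.20-fold. AT5G20790 fell 9.40-fold and AT2G04230 fell 7.34-fold. AT3G62220, AT5G37290 and AT1G67620 also fell, but their sdg8 means lay near the background. On the log2(intensity + 64) scale they differed from wild type by -2.32, -1.59 and -1.52. NRPB6B, a subunit gene of RNA polymerase, had a log2 change of -2.61 (SE 0.20).

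Gene groups also moved in sdg8. Of 5 measured genes of the flavonoid and anthocyanin list, 4 rose, with DFR, the dihydroflavonol reductase gene, at a log2 change of 1.44 and UF3GT at 0.82; adjusted over the list alone, 4 rose and 1 fell. The list shifted up (camera adjusted p = 0.00462, preset correlation), which was lost with an adjusted p = 0.107 with an estimated correlation. Of 17 cytochrome P450 genes, 5 fell and 12 did not pass the test, with CYP71B5 at -1.90 and CYP71B23 at -1.66. That list shifted down (camera adjusted p = 0.00118, or 0.0226 before false matches were removed), with an adjusted p = 0.101 with an estimated correlation. Of 9 RALF signalling peptide genes, 4 rose, by log2 changes such as 0.43 for RALFL34 and 0.40 for RALFL22 (camera adjusted p = 0.0218, and adjusted p = 0.251 with an estimated correlation). Of 67 plastid-encoded genes, 12 rose, among them petA at 0.78 and psaJ at 0.48 (camera adjusted p = 7.94e-05, and adjusted p = 0.763 with an estimated correlation). The shift of the RALF peptides was not called without wild type replicate 1 (adjusted p = 0.0850), without sdg8 replicate 2 (adjusted p = 0.130) or with a filter at the 50th percentile (adjusted p = 0.103), which also left 3 flavonoid and 4 cytochrome P450 genes, too few for a test, while the plastid-encoded genes were called (adjusted p = 0.000932). That of the plastid-encoded genes was not called with sdg8 replicate 1 as the lone sdg8 array (adjusted p = 0.0573). The cytochrome P450, RALF, plastid, autophagy and RNA polymerase lists were written after the annotation was seen. Of 4 chlorophyll synthesis genes, too few for a list test, PORB, which encodes a protochlorophyllide oxidoreductase, fell by 0.91 on the log2 scale, CHLI2 rose by 0.36, and CHLM and GSA1 did not pass, with the same calls adjusted over the list alone. CHLI2 did not pass without the variance trend, without wild type replicate 1, wild type replicate 2 or sdg8 replicate 2, or with sdg8 replicate 1 as the lone sdg8 array.

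In total 1167 probe sets rose and 1431 fell in sdg8, and 501 of the 2598 changed at least 2-fold, 113 higher and 388 lower. The share of higher among them was 44.9%, 56.7% with median centring and 33.5% with sdg8 replicate 1 as the lone sdg8 array, so at the 0.05 threshold which direction prevailed depends on the scaling. The median SD within a group on the log2 scale was 0.199 in sdg8, 0.193 in hub2, 0.191 in sdg8hub2 and 0.167 in wild type. The root mean square deviation from the group mean was 0.41, 0.46 and 0.45 on the sdg8 arrays and 0.33, 0.34 and 0.36 on those of wild type. With only the groups compared in the fit, 2660 probe sets changed here. In that setting sdg8hub2 against sdg8 gave 2320 in place of 2623, and sdg8 against hub2 gave 2340 in place of 2925. With sdg8 replicate 1 as the lone sdg8 array, a setting chosen after the data were seen that assumes it varies like the other groups, 1110 probe sets changed, and AT1G31690, LHCB4.2, UF3GT, petA, psaJ, RALFL34 and RALFL22 did not pass. AT5G20790 and AT2G04230 did not pass without the variance trend, nor AT5G20790 in the robust fit, and their log2 changes of -3.23 and -2.88 were -1.56 without sdg8 replicate 2 and -1.67 without sdg8 replicate 3. UF3GT and petA also did not pass without the trend or without wild type replicate 2, UF3GT not without sdg8 replicate 2, petA not in the robust fit, and psaJ not without the trend.

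In hub2 against wild type, PDF1.2, a defensin gene of the jasmonate and ethylene response, rose 2.90-fold, from a log2 signal of 7.84 ± 0.22 to 9.38 ± 0.01 (SD, n = 3). PDF1.2b, read by a probe set of a type that can cross-hybridise, rose 2.67-fold, AT2G32190 2.83-fold, AT1G56060 2.51-fold, AT3G53250 2.35-fold and AT3G47540 2.15-fold. AT1G67865 rose 2.14-fold and the mitochondrial heat shock gene AT5G51440 rose 2.05-fold. Falls were seen for AT3G49960 (2.67-fold), the peroxidase gene AT5G39580 (2.52-fold), AT5G27410 (2.44-fold), AT4G12500 (2.39-fold), AT2G43945 (2.38-fold), the glutaredoxin gene GRXC1 (2.35-fold), AT4G12490 (2.32-fold) and PR-1-LIKE (2.30-fold).

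Of 3 measured genes of the jasmonate and ethylene defence list, PDF1.2 and PDF1.2b rose and THI2.1 did not pass the test, and the same 2 rose when adjusted over the list alone. Of 5 light harvesting and photosystem genes, LHCB4.2 rose by a log2 change of 0.82 and 4 did not pass the test (LHCB4.1 turned from 0.07 to -0.011 with quantile normalization), and 2 rose when adjusted over the list alone. That list shifted up (camera adjusted p = 0.00136), with an adjusted p = 0.624 with an estimated correlation. Of the 4 chlorophyll synthesis genes, PORB rose by 0.57 and 3 did not pass, also adjusted over the list alone. Of 16 expansin genes, EXPA8 rose by 0.77, EXPA16 fell by 0.58 and 14 did not pass (2 rose and 1 fell adjusted over the list alone), and EXPA16 did not pass when any 1 of the wild-type or hub2 arrays or sdg8 replicate 2 was left out, with median centring, with no filter, without the variance trend or with the actin 3' minus 5' difference as a covariate. Of 11 glutathione S-transferase genes, 2 rose, also adjusted over the list alone, GSTU25 by 0.77 and GSTU20 by 0.36.

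Of the 519 probe sets changed in hub2, 254 rose and 265 fell (48.9% higher, and 51.2% without the variance trend), and 61 changed at least 2-fold, 31 higher and 30 lower. The 3' minus 5' difference of actin was 1.55 ± 0.44 in hub2 and 1.17 ± 0.13 in wild type (SD, n = 3), with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow. Replicate 2 stood apart among the hub2 arrays, at 2.06 against 1.29 and 1.31 in replicates 1 and 3, and without it the hub2 mean lay 0.13 above wild type in place of 0.39. That array also had the highest GAPDH difference (0.27) and DAP spike signal (1898 intensity units) of the 12. A second pair of actin control probe sets, not tested, gave overlapping values. They were 2.08, 3.77 and 3.26 in hub2 and 3.08, 2.85 and 3.38 in wild type, for replicates 1, 2 and 3. On a second GAPDH pair, hub2 replicate 2 stood at 1.66 and the other arrays at 0.35 to 0.84. The count fell to 233 with the first actin difference as a covariate. It fell to 127 without the variance trend and to 340 with median centring, and rose to 835 with array weights. It was 210, 294 and 247 without wild type replicates 1, 2 and 3, and 332 and 338 without hub2 replicates 2 and 3. AT2G32190, AT1G56060, AT5G27410, AT3G49960 and GSTU20 each lost their call without several of the wild-type or hub2 arrays taken singly, without the variance trend and with the covariate, AT5G51440 without the trend and with the covariate, AT4G12500 without the trend, and GSTU20 with median centring. The plastid-encoded genes, not called here (adjusted p = 0.551), had an adjusted p = 0.0376 without wild type replicate 2 and 0.0150 without hub2 replicate 3.

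In the double mutant against wild type, AT2G21640 rose 23.1-fold, to a log2 signal of 11.94 ± 0.23 (SD, n = 3). AT5G09570 rose 21.9-fold, AT2G41730 15.4-fold and AT5G51440 12.7-fold. NDB4, which encodes an alternative NAD(P)H dehydrogenase of mitochondria, AT3G28310, AT2G03130 and AT5G40040 rose from wild-type means near the background, and on the log2(intensity + 64) scale they rose by 3.11, 2.20, 2.37 and 1.60. AT1G36390, a gene for a GrpE-type co-chaperone, fell 7.28-fold, from 8.82 ± 0.11 to 5.95 ± 0.16 (SD, n = 3), and its neighbour AT1G36380 fell 7.02-fold. GAT1_2.1, a glutamine amidotransferase gene, fell 9.17-fold on 1 probe set, while its other probe set had a log2 change of -1.47 that did not pass (adjusted p = 0.222). Falls were also seen for NRPB6B (6.85-fold), AT3G62220 (6.09-fold) and AT5G27410 (4.43-fold). AT3G45700 and AT5G37290 fell to means near the background, by -1.53 and -1.69 on the log2(intensity + 64) scale.

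PDF1.2 fell in sdg8hub2 by 1.48 and PDF1.2b by 1.33 on the log2 scale, so 2 of the 3 jasmonate and ethylene defence genes fell, also when adjusted over the list alone. COR15B and COR15A, cold-response genes, fell by 0.97 and 0.46, and COR47, the other measured member of the cold and ABA list, did not pass, so 2 of 3 fell, also adjusted over the list alone. Of 16 expansin genes, 2 rose and 4 fell, in the same numbers adjusted over the list alone, with EXPA16 at -1.26 and EXPA4 at 0.49. Of 11 glutathione S-transferase genes, 4 rose and 2 fell, in the same numbers adjusted over the list alone, with GSTU25 at 2.08 and GSTU26 at -0.83. Of 12 RNA polymerase subunit genes, 4 rose and 1 fell, with NRPB12 at 0.81 and NRPB6B at -2.78. Of the 29 lists tested, 0 passed camera in this comparison (1 at an unadjusted p under 0.05), and fry called 5. In total 1457 probe sets rose and 1910 fell, 603 of them by at least 2-fold (219 higher and 384 lower), and the share of higher, 43.3%, was 57.4% with median centring. COR15A did not pass with median centring, without the variance trend or without wild type replicate 1, wild type replicate 3 or sdg8hub2 replicate 1, and the RNA polymerase subunits were called without the trend (adjusted p = 0.0225). GAT1_2.1, at -3.20 on the log2 scale, had -2.49 without sdg8hub2 replicate 1 and -3.95 without sdg8hub2 replicate 2.

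**Figure D2:**
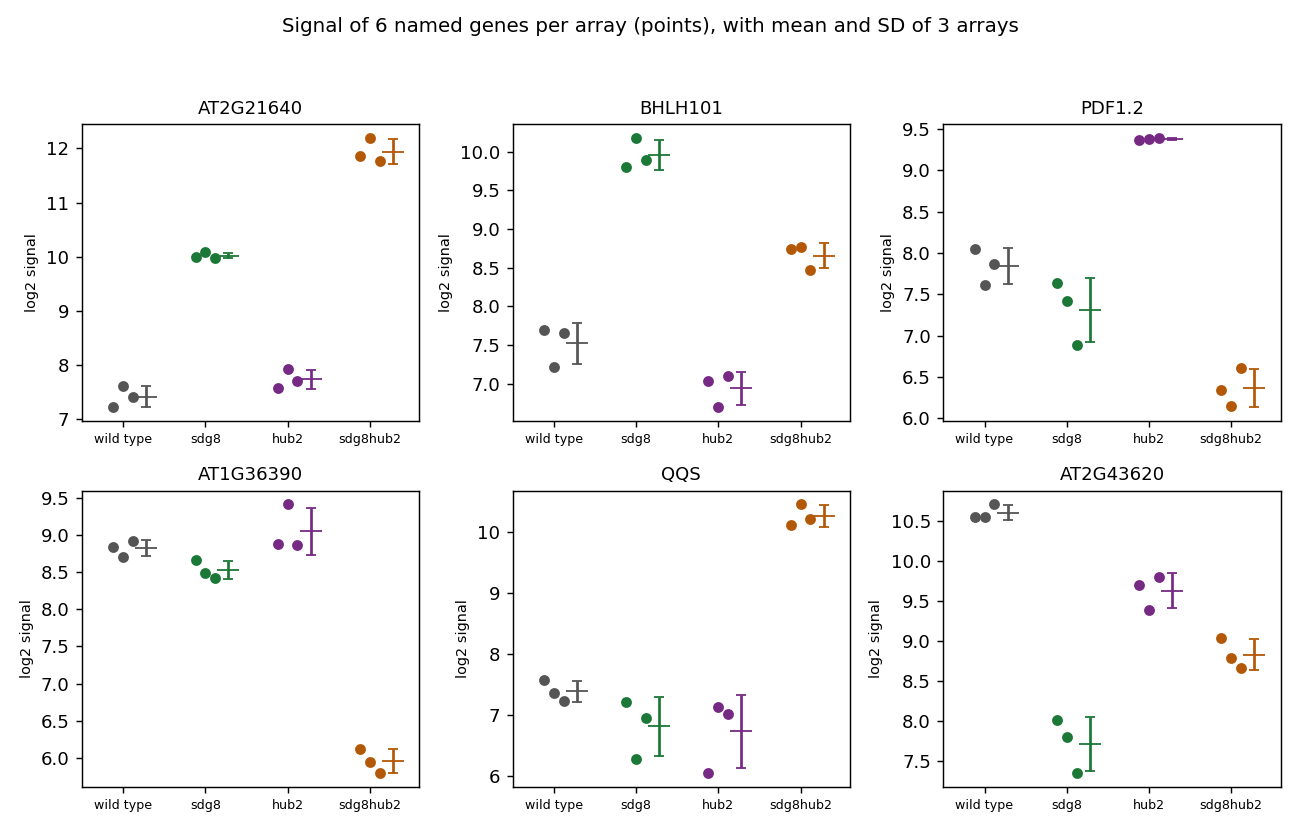
Log2 signal (y axis) of 6 genes on each of 12 arrays (points, 3 per group on the x axis), with the mean and SD of each group beside them. AT2G21640 stood at 7.41 in wild type, 10.02 in sdg8 and 11.94 in sdg8hub2, and AT1G36390 stood at 8.82 in wild type and 5.95 in sdg8hub2.

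The double mutant was then set against each single mutant. Against sdg8, QQS, a gene of starch metabolism, was 10.8-fold higher, AT5G60250 6.78-fold, AT3G61930 6.20-fold, NDB4 6.08-fold and AT2G04070 5.60-fold. GAT1_2.1 was 11.1-fold lower (with a log2 difference of -0.92 on its other probe set, which did not pass), AT1G36390 5.94-fold, the glutaredoxin gene AT2G47880 5.87-fold, the sugar transporter gene SWEET4 4.30-fold and AT1G36380 3.81-fold. Of the 5 flavonoid and anthocyanin genes, 3 were lower than in sdg8 (4 adjusted over the list alone), with DFR at -1.32 (camera adjusted p = 0.000426, and adjusted p = 0.0798 with an estimated correlation). Of the 67 plastid-encoded genes, 16 were lower (camera adjusted p = 3.13e-07, and adjusted p = 0.556 with an estimated correlation). Of 11 autophagy genes, 4 were higher, among them ATG8B at 1.08 (camera adjusted p = 0.0154, and adjusted p = 0.556 with an estimated correlation). The total was 2623 probe sets, 1219 higher and 1404 lower, while of the 431 that differed at least 2-fold 262 were higher and 169 lower. The share of higher, 46.5%, was 50.3% with quantile normalization and 53.9% with sdg8 replicate 1 as the lone sdg8 array, so which direction prevailed depends on the processing. The count was 971 with sdg8 replicate 1 as the lone sdg8 array. In that setting AT3G61930 did not pass, with a log2 difference of 1.71 in place of 2.63 (also 1.71 without sdg8 replicate 2), and NDB4 stood at 3.20 in place of 2.60, while AT2G47880 turned from -2.55 to -1.93 without sdg8hub2 replicate 2. The autophagy genes were not called there (adjusted p = 0.248), without sdg8 replicate 3 (adjusted p = 0.126) or without sdg8hub2 replicate 2 (adjusted p = 0.0966).

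Against hub2, AT5G09570 was 27.4-fold higher in the double mutant, AT2G21640 18.4-fold, AT2G03130 16.5-fold, NDB4 15.4-fold and AT3G28310 13.1-fold. GAT1_2.1 was 13.3-fold lower (-1.04 on its other probe set, which did not pass), AT1G36390 8.56-fold, PDF1.2 8.07-fold and AT3G28220 8.03-fold. AT5G37290 was lower with a double-mutant mean near the background (-1.62 on the log2(intensity + 64) scale). Of the 29 lists, 0 passed camera (2 at an unadjusted p under 0.05), and fry called 4. Here 1305 probe sets were higher and 1793 lower, 3098 in all (185 and 320 at 2-fold or more), and the share of higher, 42.1%, was 59.0% with median centring. The light harvesting and photosystem proteins were called as lower with quantile normalization (adjusted p = 0.0441) and without hub2 replicate 2 (0.0293), hub2 replicate 3 (0.0467) or sdg8hub2 replicate 1 (0.0496), and the plastid-encoded genes without hub2 replicate 3 (0.0234). AT3G28310 stood 2.83 higher on the log2 scale, in place of 3.71, without hub2 replicate 1.

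Between the single mutants, BHLH101 was 8.07-fold higher in sdg8 than in hub2, AT5G09570 6.99-fold, PR-1-LIKE 5.38-fold, AT5G05250 4.96-fold and AT2G21640 4.88-fold. AT2G41120 was 8.31-fold lower in sdg8. AT3G62220, AT1G56060, AT1G67620 and AT5G37290 were lower with sdg8 means near the background, by -1.96, -1.78, -1.49 and -1.52 on the log2(intensity + 64) scale. Of the 5 flavonoid and anthocyanin genes, 4 were higher in sdg8 and 1 lower, in the same numbers when adjusted over the list alone (camera adjusted p = 0.00109, and adjusted p = 0.102 with an estimated correlation). Of the 17 cytochrome P450 genes, 6 were lower in sdg8 (camera adjusted p = 0.00817, or 0.0256 before false matches were removed, and adjusted p = 0.102 with an estimated correlation). Of the 9 RALF genes, 5 were higher (camera adjusted p = 0.00295, and adjusted p = 0.102 with an estimated correlation). Of the 11 autophagy genes, 3 were lower (camera adjusted p = 0.00906, and adjusted p = 0.664 with an estimated correlation), and of the 67 plastid-encoded genes, 7 were higher (camera adjusted p = 0.00109, and adjusted p = 0.699 with an estimated correlation). The total was 2925 probe sets, 1336 higher and 1589 lower in sdg8 (45.7% higher, and 59.4% with median centring). At 2-fold or more 122 were higher and 390 lower, and the total was 1203 with sdg8 replicate 1 as the lone sdg8 array. Without sdg8 replicate 3 the cytochrome P450 genes (adjusted p = 0.0502) and the autophagy genes (adjusted p = 0.0928) were not called, nor with the actin covariate (0.0503 and 0.0698). With the lone array neither the autophagy genes (adjusted p = 0.273) nor the plastid-encoded genes (adjusted p = 0.179) were called, and the latter were not without hub2 replicate 3 (adjusted p = 0.107).

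The interaction asks whether the effect of sdg8 differed between the hub2 and the wild-type background, and 1175 probe sets passed, 555 above and 620 below additivity (186 and 157 at 2-fold or more). Which side prevailed depends on the processing, as the share above, 47.2%, was 52.0% with quantile normalization, 53.8% with median centring and 57.0% with sdg8 replicate 1 as the lone sdg8 array. QQS stood 4.09 log2 units above additivity (SE 0.35), AT3G61930 3.14, AT5G60250 2.49 and CHI, a putative chitinase gene, 2.42. AT3G62220 stood 3.68 above, with an sdg8 mean near the background (1.02 on the log2(intensity + 64) scale). GAT1_2.1 stood at -4.01 on 1 probe set and at -0.49 on its other one, which did not pass (adjusted p = 0.864). Lower values were also those of AT2G47880 (-2.97), AT1G36390 (-2.80), SWEET4 (-2.51) and PDF1.2 (-2.48). Of the 3 cold and ABA genes, COR15B lay below, at -1.60 (2 adjusted over the list alone), and of the 16 expansin genes 3 did (4 adjusted over the list alone), with EXPA8 at -1.02. Of the 5 light harvesting and photosystem genes, 3 lay below additivity, in all and adjusted over the list alone, with LHCB4.2 at -0.57 (camera adjusted p = 0.00231, and adjusted p = 0.307 with an estimated correlation). Of the flavonoid and anthocyanin genes, DFR lay below, and 3 of 5 did adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.307 with an estimated correlation). Of the 67 plastid-encoded genes, 9 lay below (camera adjusted p = 1.23e-06, and adjusted p = 0.494 with an estimated correlation). Of the 1175 probe sets, 479 had changed in neither single mutant, and 289 of those changed in the double mutant. Without the variance trend the count was 530, and AT3G61930 and LHCB4.2 did not pass, and with sdg8 replicate 1 as the lone sdg8 array it was 528, and AT3G61930 and DFR did not pass. AT3G61930 also did not pass with the actin covariate or without wild type replicate 3, sdg8hub2 replicate 1 or sdg8hub2 replicate 3.

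The single mutants shared 247 changed probe sets, 87 higher in both, 117 lower in both and 43 in opposite directions. Examples are AT5G51440, higher in both, and AT5G39580, AT4G12500 and AT4G12490, lower in both, while PORB and LHCB4.2 fell in sdg8 and rose in hub2. Independent lists would share 16.3 higher and 20.8 lower, and unchanged groups against the same wild-type arrays shared 0.05 on average in simulation. Almost no probe set is called in unchanged groups, so that simulated overlap cannot show what the shared arrays add when many are called. Part of the excess may come from the shared wild-type arrays. The number shared in the same direction, 204, was 96, 120 and 117 without wild type replicates 1, 2 and 3, 68 without the variance trend, 105 with the actin covariate and 122 with sdg8 replicate 1 as the lone sdg8 array. Across genes, which are not independent replicates, the log2 changes had r = 0.35 against 0.50 in simulated unchanged groups, and a covariance of 0.0786 against 0.0691. For sdg8 and sdg8hub2 the covariance was 0.161 against 0.0692, and for hub2 and sdg8hub2 it was 0.0900 against 0.0690. These simulations gave all arrays of a probe set the same spread. Wild type had the smallest median SD within a group, so the simulated covariances may be too high. The simulated r holds for groups without changes, so an r below it does not measure how much the mutants share.

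Over the 2870 probe sets changed in a single mutant, the double mutant's log2 change followed the sum of the single mutants' changes with a slope of 0.513 and r = 0.752. With additive effects simulated from the shrunk single-mutant changes, a method revised after its 1st result was seen, the slope averaged 0.771 and ranged from 0.746 to 0.798. The sign matched the sum for 85.0% of these probe sets, against 98.7% in simulation, where r averaged 0.936. The simulations called 3340 probe sets on average, more than in the data, and gave all arrays of a probe set the same spread. Both may raise the simulated slope, r and share of matching signs, so the size of the gap to the data is not settled.

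As a sign of RNA quality, the 3' minus 5' differences of actin and GAPDH in each mutant were set against wild type. The smallest exact permutation p of the 6 comparisons was 0.1, for actin in hub2 as above, and the smallest Benjamini-Hochberg adjusted p was 0.6. With 3 against 3 arrays no p can fall below 0.1, so a difference is not excluded.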

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

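The mitochondrial gene list and its tests, both tests of the gene pair AT1G36380 and AT1G36390, and the actin covariate were chosen only after results they measure had been seen, and the permutation of residuals was added after the interaction count was known.

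The effect of sdg8 differed between the hub2 and the wild-type background for 1175 probe sets (limma interaction, Benjamini-Hochberg). Of 100 drawn splits of the 12 arrays, the real one included, 1 gave as many, and the highest of the others gave 231, but such splits also mix the main effects, which widens the spread and lowers their counts. In a second test the residuals of the additive fit were instead permuted over the arrays and added back to it. There 1 of 100 data sets, the real one included, gave as many, and the highest of the others gave 4. Those residuals still hold the interaction itself, which widens the spread and lowers the permuted counts too. The permutation also treats all arrays alike, while the sdg8 arrays varied most. The real count lay above all permuted ones, but chance is not excluded as a source of part of it. The difference was positive for 16 of the named genes: QQS 4.09, AT3G62220 3.68, AT3G61930 3.14, AT5G60250 2.49, CHI 2.42, AT5G09570 2.29, AT2G04070 2.23, AT2G43620 2.09, AT5G39580 2.07, AT2G41120 1.92, AT4G12500 1.69, AT2G21640 1.59, AT2G41730 1.24, AT4G12490 1.09, AT2G43945 0.92 and GRXC1 0.86 log2 units. It was negative for 12: GSTU25 -0.63, AT3G47540 -0.96, AT1G67865 -1.11, AT5G14650 -1.31, AT1G36380 -1.89, AT3G28220 -1.98, PDF1.2b -2.06, PDF1.2 -2.48, SWEET4 -2.51, AT1G36390 -2.80, AT2G47880 -2.97 and GAT1_2.1 -4.01, whose other probe set had -0.49 and did not pass. The chitinase family gene AT2G43620 and the peroxidase gene AT5G39580 had sdg8 effects of -2.89 and -2.64 in the wild-type background and of -0.80 and -0.57 in the hub2 background.

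For the 6 pairwise comparisons, 10 splits of 6 arrays are too few for a share under 0.05. The real split (1 of the 10 in each) gave 2598, 519 and 3367 probe sets for sdg8, hub2 and sdg8hub2 against wild type, and 2623, 3098 and 2925 for sdg8hub2 against sdg8, sdg8hub2 against hub2 and sdg8 against hub2. The highest of the other splits gave 0, 1, 0, 1, 1 and 0 probe sets, in that order. Those splits mix both groups, so any real difference widens the spread and lowers their counts, and no conclusion is drawn from them.

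One pattern concerns genes held from general knowledge to respond to mitochondrial dysfunction, 14 measured and named of 31 looked up, a list written after the values were seen, first without NDB3 and AT1G21520, and so no independent evidence. In sdg8hub2, 13 of the 14 rose, with a median log2 change of 3.24, against 9 with a median of 1.37 in sdg8 and 3 with a median of 0.33 in hub2. Members such as NDB4 and AT2G03130 rose from wild-type means near the background, so the size of these medians depends in part on the background. Array scaling is argued against as the cause by a median of 3.29 after quantile normalization, while RNA quality stays open: the median was 3.24 with the actin 3' minus 5' difference as a covariate, but that difference was only 0.13 larger in sdg8hub2 than in wild type, too little to move the median. Of the 14 genes, 13 were higher in sdg8hub2 than in sdg8 and 8 lay above additivity, but these counts test nothing, since the genes were listed for their values. An effect of losing both SDG8 and HUB2 and growth differences between the lines stay open and were not tested.

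Another pattern concerns the adjacent genes AT1G36380 and AT1G36390, which fell 7.02-fold and 7.28-fold in the double mutant. Signal shared between their probe sets was tested by their log2 changes in sdg8, which differed by 0.59 (SE 0.23). That SE took the 2 probe sets as independent, though both were read on the same arrays. Probe sets that differ in background may also change unequally with a shared signal, so this explanation stays open. A change of the wider neighbourhood stays open, because only 4 of the genes within 20 on either side were measured and named, and 0 of them fell by 2-fold or more. A local difference carried by the double-mutant line might give such a pair, and no value here decides it.

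A last pattern is the upward shift in the signal of 67 plastid-encoded genes in sdg8, with a median log2 change of 0.24. Whether signal on these 3' arrays follows the transcript level of plastid-encoded genes was not tested, here or in the other comparisons. A single sdg8 array as the cause is argued against by medians of 0.31, 0.22 and 0.25 without sdg8 replicates 1, 2 and 3. The highest was that without replicate 1, so replicates 2 and 3, which lay at opposite ends of the third principal component, carry more of the shift, and with replicate 1 as the lone sdg8 array the list was not called (adjusted p = 0.0573). A shift confined to those replicates was not tested and stays open. After quantile normalization the median was 0.20 (SE 0.057). That SE comes from resampling the 67 genes, which are not independent replicates, and leaves out the spread between arrays. The median lay within 2 SE of the bound of 0.1 fixed beforehand, so array scaling stays open. RNA quality stays open too: the median was 0.24 with the actin covariate, which differed by only 0.063 between sdg8 and wild type and could hardly move it. The list was not called with an estimated correlation, and an effect of the sdg8 mutation stays open and untested.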

How the results depend on the processing

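The settings with sdg8 replicate 1 as the lone sdg8 array (assumed to vary like the other groups) and with the actin covariate were chosen after the data were seen. Counts are given in the order sdg8, hub2 and sdg8hub2 against wild type, sdg8hub2 against sdg8, sdg8hub2 against hub2, sdg8 against hub2, and interaction. At an adjusted p under 0.01 they were 1414, 181, 2044, 1397, 1717, 1585 and 482, and with at least 2-fold 501, 61, 603, 431, 505, 512 and 343. Without 1 array they ranged over 1768 to 2862, 210 to 554, 2450 to 3642, 2003 to 2886, 2262 to 3253, 2159 to 2933, and 805 to 1146. The lone sdg8 array gave 1110 for sdg8, 971 and 1203 for sdg8hub2 against sdg8 and sdg8 against hub2, and 528 for the interaction. For hub2, median centring gave 340, no variance trend 127, array weights 835 and the actin covariate 233; the interaction without the trend gave 530. Other settings kept each count within 1.5 times. Median centring moved the share of higher calls by over 10 percentage points in sdg8 and sdg8hub2 against wild type and in sdg8hub2 and sdg8 against hub2 (to 56.7%, 57.4%, 59.0% and 59.4%), and the lone sdg8 array moved that of sdg8 to 33.5%. Stricter thresholds call fewer by construction, and for all other changes given here the cause was not tested. Of the calls of named genes, quantile normalization ended 34 and added 7, and median centring ended 58 and added 9. The fit without the variance trend ended 128 and added 5, and the actin covariate ended 47 and added 15. No filter ended 35 and added 1, and a fit of only the groups compared ended 36 and added 7. Summed over all fits without 1 array, 649 calls ended and 60 were added. Signal over background limits the folds of dim genes: AT3G62220 had -5.84 in sdg8, and -2.32 with a pseudocount of 64.

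The number of probe sets shared in the same direction by sdg8 and hub2 was 204, and 80 at 0.01, 30 with 2-fold, 68 without the trend, 105 with the actin covariate, 122 with the lone sdg8 array and 96 to 195 without 1 array. The additivity slope of 0.513 was 0.455 without a filter, 0.557 with the filter at the 50th percentile, 0.546 and 0.556 with pseudocounts of 16 and 64, 0.419 with the lone sdg8 array and 0.429 to 0.543 without 1 array.

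The same-numbered arrays did not deviate together (r from -0.13 to 0.04 over 18 pairs, 0 of them above 0.1), and 2 of 12 arrays correlated best with their own number, so the numbers do not pair the arrays. With the replicate number as a block the counts were 2486, 448, 3264, 2543, 3012, 2834 and 1083, the shared number 176 and the slope 0.521.

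Lists called numbered 4, 1, 0, 3, 0, 5 and 3, and 0 in each comparison with an estimated correlation. The 50th percentile filter, which left the flavonoid and cytochrome P450 lists too small to test, gave 1 in sdg8 and 3 in sdg8 against hub2, where the lone array and the actin covariate also gave 3; the covariate gave 5 for the interaction. The fit without the trend gave 1 in sdg8hub2, and quantile normalization 1 in sdg8hub2 against hub2. Fry called 5 in sdg8hub2, 6 and 4 in sdg8hub2 against sdg8 and hub2, and 9 in sdg8 against hub2. Without 1 array, 1 to 2 were called in hub2, 0 to 2 in sdg8hub2 against hub2 and 3 to 5 in sdg8 against hub2.

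Sign changes touched list members that had not passed: LHCB4.3 in sdg8 (0.045) and in sdg8hub2 against sdg8 (-0.068) with the lone array, LHCB4.1 in hub2 (-0.011) and PSBY in sdg8 against hub2 (-0.0071) with quantile normalization, and PSBY there with the lone array (-0.016). THI2.1 in sdg8hub2 against hub2 gave 0.060 with median centring, 0.0021 with a pseudocount of 64, 0.0080 with the covariate and -0.76 to 0.45 without 1 array; it ranged over -0.045 to 1.15 in sdg8 against hub2, and in the interaction gave -0.070 with quantile normalization and -0.67 to 0.54 without 1 array. Without 1 array, AT1G33440 in sdg8hub2 ranged over -0.81 to 0.012, and in sdg8hub2 against hub2 AT4G14090 over -0.043 to 0.43 and AT2G46140 over -0.0011 to 0.24.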

Other observations

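Further genes, chosen after their values were seen, moved in sdg8 and hub2 in opposite directions. AT1G47400, a small peptide gene of the iron deficiency response, had a log2 change of 1.43 in sdg8, -0.67 in hub2 and 0.78 in sdg8hub2 (limma adjusted p = 1.78e-09, 0.000385 and 7.65e-06). AT5G05250 went the same way, at 1.66, -0.65 and 0.96. BHLH101, which rose in sdg8, had -0.58 in hub2, which did not pass (adjusted p = 0.0605). Neither gene had an interaction that passed (adjusted p = 0.964 for AT1G47400 and 0.927 for AT5G05250).

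The histone H2B gene HTB4, also chosen after its values were seen, rose in hub2 by a log2 change of 0.47 and in sdg8hub2 by 0.61, and had -0.07 in sdg8, which did not pass.

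The sdg8 arrays 2 and 3 lay at opposite ends of the third principal component, at 49.4 and -58.3, and the other 10 arrays lay between -7.79 and 7.10. That component held 10.7% of the variance.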
